A study of Homo sapiens with 2 samples.

How the data were processed

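The data came from a pooled CRISPR interference screen in PaTu8902 cells, a human pancreatic adenocarcinoma line, per the labels. The cells stably expressed dCas9-KRAB, a Cas9 protein without cutting activity joined to a repressor domain, so that each single guide RNA (sgRNA) lowers transcription from the promoter it is directed to. Cells were stained for surface MHC class I, and the 30% with the lowest and the 30% with the highest staining were collected by fluorescence-activated sorting. One sequencing library was made from the sgRNA cassettes in the genomic DNA of each sort. The samples therefore form 2 groups, MHC-I low and MHC-I high, with 1 library in each. An unsorted population or the plasmid pool was not analysed here.

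The deposited table holds raw counts of reads per sgRNA for both libraries, whole numbers with no normalization. Per the file headers, which fill 4 lines, the reads were trimmed and matched to the human CRISPRi v2 guide library before they were counted. The tool that trimmed and matched the reads is not given in the sources used here. R 4.3.1 is listed in the submitters' processing notes, with no role. The guide names give a gene symbol, a strand, a position and a promoter label (P1, P2 or both), but no chromosome, and the genome build is not given in the sources used here. Positions are therefore printed only as the guide names give them. Of the 18902 gene symbols with a tested target, 17438 were current symbols in the RefSeq gene table of assembly GRCh38.p14, 1374 were found only as synonyms there and 90 were in neither. That table was used for names, for the chromosome of each gene in the search for neighbouring targets, and for the reading of the symbol NAA38. The guides named NAA38 were read as LSM8, since NAA38 is an older symbol of LSM8 and the positions in the guide names lie beyond the last gene of the chromosome that carries NAA38 in RefSeq.

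Both libraries were scaled to their mean total. For each guide, 10 reads were added to both counts and log2(MHC-I high / MHC-I low) was taken, then centred on the median of the non-targeting guides. A negative value means that the guide was more frequent among MHC-I low cells, and a positive value that it was more frequent among MHC-I high cells. The added reads pull the values of guides with few reads towards 0. Guides with fewer than 100 reads over both libraries were left out. A target was a gene together with the promoter its guides were designed for, and needed at least 3 kept guides. The mean over the guides of a target was compared with the means of equally many non-targeting guides drawn 100000 times, as a two-sided permutation test with Benjamini-Hochberg adjustment over 20525 targets. A target was called at an adjusted p of 0.05. The smallest p that the draws can give is 2e-05. With 1 library per sort, no count model with an estimate of the spread between samples could be fitted. The guides are separate constructs read in the same 2 libraries, so the standard errors and p-values describe the spread between guides in these 2 libraries and say nothing about repeated sorts. Read counts come from PCR products without molecular identifiers, so they are not independent molecules.

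The sequencing depth was 153131291 counted reads for MHC-I low and 142727562 for MHC-I high. The median guide had 1315 and 1231 reads. Precision depended on the reads behind a guide. The SD of the non-targeting guides was 0.81 in the fifth with the fewest reads, which had a median of 478 reads, and 0.29 in the fifth with the most, which had a median of 2399 reads.

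The genes to be named were chosen by a rule written before the data were examined. They were the 12 lowest and the 12 highest called targets with at least 75% of their guides on the side of the mean, the stained protein's own genes whatever their values, and up to 4 called members per direction of each of 22 gene lists. Results for some genes that the rule names or a list holds are not reported here. The lists were fixed at the same time, as were the main test and most alternatives. They covered MHC-I heavy chains and B2M, peptide loading, MHC-I gene transcription, interferon and JAK-STAT signalling, NF-kB signalling, the proteasome, ER-associated degradation, N-glycan assembly, core autophagy, autophagy and ER-phagy receptors, lysosome acidification, ER export, Sec61 and SRP, UFMylation, the unfolded protein response, surface MHC-I turnover, glycosphingolipid synthesis, chromatin repressors, EGFR, RAS and MAPK signalling, mTORC1 signalling, cytosolic ribosomal proteins and olfactory receptors. The ribosomal list stood for genes needed for growth and the olfactory list for genes with no known role in epithelial cells. A list was described by the median over its members (primary promoter) and the percentile of that median among 10000 random lists of the same size matched on read count in 10 bins. For the percentiles in alternative settings, fewer random lists were drawn. Calls within a list are also given adjusted over the list alone. Another 6 lists were assembled after the called targets had been seen and are named as such where they appear.

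The scoring was tested on simulated data for this comparison, with 200 of 20528 targets changed and noise drawn from the non-targeting guides. A log2 change of 2 was recovered for 100% of targets when all guides acted and for 76% when 3 of 5 guides acted. A change of 1 was recovered for 54% and 0% of targets. Of 20325 unchanged targets, 10 were called, beside 115 changed ones, so false calls made up 8% of the simulated calls. Alternatives changed the count filter, the pseudocount, the centring, the null distribution, the statistic per target, the target definition and the threshold. Alternatives with more draws, with guide values divided by the SD of the non-targeting guides in the same 1 of 5 bins of read count, and with each guide set against the 30 non-targeting guides nearest in read count were added after the data had been seen. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.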

Results

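The screen asked which promoters, when repressed, changed the amount of MHC class I on the surface of PaTu8902 pancreatic adenocarcinoma cells. MHC class I presents peptides to T cells and consists of a heavy chain and beta-2-microglobulin. Guide counts were available for 1 library of MHC-I low cells, with 153131291 reads, and 1 library of MHC-I high cells, with 142727562 reads. There was no replicate sort. The library held 104535 guides, of which 1895 were non-targeting and the rest formed 20528 targets of 5 guides for 18905 genes. In all, 0.99% of guides had no read in MHC-I low and 0.98% in MHC-I high, and non-targeting guides took 1.77% of the reads in each. After guides with few reads were left out, 103106 guides and 20525 targets remained. Values are log2(MHC-I high / MHC-I low) per target, given as mean ± SE over 5 guides unless another number is stated.

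Guides against B2M, NLRC5 and TAP1 were more frequent in MHC-I low than in MHC-I high cells, and so were guides against the splicing factor genes SF3A2 and LSM6 and the proteasome gene PSMD4. B2M encodes beta-2-microglobulin, NLRC5 is the transcriptional activator of MHC class I genes, and TAP1 is a subunit of the transporter that brings peptides into the endoplasmic reticulum (ER). In the other direction, guides against CASP8AP2, the transcription factor gene JUNB and the glycosyltransferase gene B3GNT2 were enriched in MHC-I high cells. Over the whole library, 34 targets were called in the MHC-I low direction and 17 in the MHC-I high direction by the permutation test against non-targeting guides. This balance depended on the processing: the counts were 52 low and 82 high with at least 500 reads per guide over both libraries, and 3 and 11 with a pseudocount of 1. At an unadjusted p of 0.05 in the same permutation test, 659 and 700 targets passed. The non-targeting guides had an SD of 0.49, with 95% of them between −0.89 and 0.95, and the targeting guides an SD of 0.51.

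**Figure D1:**
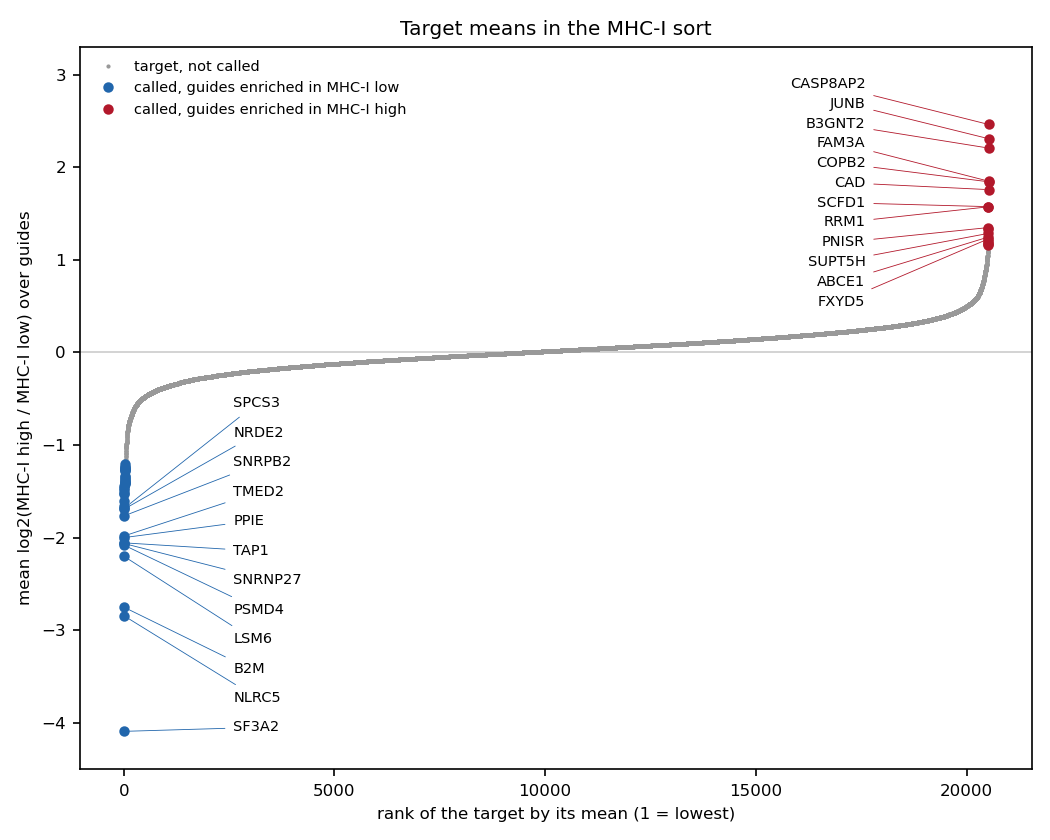
Mean log2(MHC-I high / MHC-I low) of each of 20525 targets (vertical axis) against its rank (horizontal axis). Blue points are the 34 called targets enriched in MHC-I low and red points the 17 enriched in MHC-I high. The 12 named at each end run from SF3A2 at −4.09 to CASP8AP2 at 2.46.

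The stained protein's own genes gave the check on the sort. The guides at the first B2M promoter, at positions 45003739 to 45004135 in the guide names, had a mean of −2.75 ± 0.73, a 6.73-fold excess in MHC-I low, and all 5 lay below 0 (permutation p = 2e-05, the smallest the draws can give, adjusted p = 0.0147). The guides at the second annotated B2M promoter, at positions 45007848 to 45008269, had a mean of −0.18 ± 0.36 and were not called (adjusted permutation p = 0.937). Among the heavy chains, HLA-B (−0.32 ± 0.45) and HLA-C (−0.17 ± 0.18) passed neither over all targets, with adjusted permutation p-values of 0.85 and 0.939, nor adjusted over the list alone. HLA-B moved to 0.11 when the median of its guides was used and the second B2M promoter to 0.09 without its farthest guide, so neither has a settled direction. The HLA genes are close copies of one another, so guides named for one heavy chain may also match another, and their values are uncertain. Over the 7 members of the list of heavy chains and B2M, the median was −0.22, at the 0.68th percentile of random lists, with 5 members below 0 and B2M called over all targets and adjusted over the list alone. That median moved to −0.10 with the median of the guides and to −0.06 without the farthest guide of each target, both inside the range of random lists.

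Genes that control MHC class I transcription lay towards MHC-I low as a group, and the peptide transporter gene TAP1 was called in the same direction. NLRC5 had a mean of −2.84 ± 0.25, a 7.17-fold excess in MHC-I low, with 5 of 5 guides below 0 (permutation p = 2e-05, adjusted p = 0.0147). In the list of 12 MHC-I transcription genes, 10 were below 0 and the median was −0.29, lower than in any random list. NLRC5 alone was called over all targets, and 3 members were called adjusted over the list alone: NLRC5, RFX5 (−0.91 ± 0.31), a subunit of the RFX promoter-binding complex, and the interferon regulatory factor IRF1 (−0.71 ± 0.33). TAP1 had a mean of −2.06 ± 0.56 with 5 of 5 guides below 0 (permutation p = 2e-05, adjusted p = 0.0147). Its partner TAP2 had a mean of −0.90 ± 0.27 and was called only adjusted over the list alone (adjusted permutation p = 0.211 over all targets and 0.0072 over the list). The gene PSMB9, whose guides lie within 489 bp of the TAP1 guides, had a mean of −0.29 ± 0.16 and was not called. The 9 genes of peptide loading and trimming had a median of −0.11, at the 4.43rd percentile and inside the range of random lists, with 7 below 0. The ER chaperones CANX (−0.08 ± 0.15) and CALR (0.27 ± 0.25), chosen after their values were seen, were not called.

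Proteasome subunits, which generate the peptides that MHC class I binds, lay towards MHC-I low as a group. Of 37 members, 29 were below 0, and the median of −0.37 was lower than in any random list. It moved to −0.22 with the median of the guides and to −0.15 without the farthest guide, again lower than in any random list. PSMD4, a ubiquitin receptor of the 19S regulatory particle, had a mean of −2.08 ± 0.28 with 5 of 5 guides below 0 (permutation p = 2e-05, adjusted p = 0.0147). PSMB2, a subunit of the 20S core, had a mean of −1.47 ± 0.41 over 4 guides (permutation p = 4e-05, adjusted p = 0.0216), which moved to −1.06 and was no longer called under the 500-read filter. These 2 were called over all targets, and 15 members, all below 0, were called adjusted over the list alone. The 18 subunits of the 19S particle had a median of −0.58, with 16 below 0, and the 17 of the 20S core a median of −0.21, with 12 below 0. This split was not among the lists fixed in advance and is descriptive only. The immunoproteasome subunits PSMB8 (−0.21 ± 0.14) and PSMB9 were not called. PSMB5 lay highest, at 0.50 ± 0.11, and was not called. Proteasome guides had a median count of 89.1% of that of non-targeting guides in the sorted libraries. Whether a general loss of fitness adds to the shift of this list was not tested.

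Several of the lowest targets encode splicing factors. SF3A2, a subunit of the U2 small nuclear ribonucleoprotein (snRNP), had the lowest mean of all targets, −4.09 ± 0.56 at its first promoter, a 17.1-fold excess in MHC-I low with 5 of 5 guides below 0 (permutation p = 2e-05, adjusted p = 0.0147). It rested on 3955 reads in MHC-I low and 240 in MHC-I high, and its second promoter had a mean of −0.37 ± 0.10 and was not called, with −2.23 for both promoters pooled. LSM6, of the LSm ring on U6 RNA, had a mean of −2.20 ± 0.18. The U4/U6.U5 protein SNRNP27 had a mean of −2.06 ± 0.63, the cyclophilin PPIE −2.00 ± 0.58 and the U2 protein SNRPB2 −1.76 ± 0.18, with 4, 4 and 5 of 5 guides below 0. NRDE2, a nuclear RNA surveillance factor, had a mean of −1.69 ± 0.30 over 4 guides. Each of these had a permutation p of 2e-05 (adjusted p = 0.0147). LSM6 and NRDE2 had mean counts of 314 and 207 reads per guide, and neither kept enough guides to be tested under the 500-read filter. Of the 34 called targets in the MHC-I low direction, 15 belonged to a list of 70 spliceosome genes assembled after the calls had been seen, a list that holds 75 of the 20525 targets. Because the calls prompted it, the list is no independent evidence of a theme.

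Early secretory genes were called in both directions. TMED2, a cargo receptor of vesicles between the ER and the Golgi, had a mean of −1.98 ± 0.36 with 5 of 5 guides below 0 (permutation p = 2e-05, adjusted p = 0.0147). GBF1, which activates the small GTPase ARF1 at the Golgi, had a mean of −1.34 ± 0.22 (permutation p = 6e-05, adjusted p = 0.0293). In the same list COPB2, a coatomer subunit, had a mean of 1.84 ± 0.56 with 5 of 5 guides above 0 (permutation p = 2e-05, adjusted p = 0.0147). The 28 members had a median of −0.05, at the 6.43rd percentile, with 16 below 0 and 12 above. Adjusted over the list alone, 3 members were called low, with TMED10 (−0.78 ± 0.53) as the third, and 6 were called high, all of them coatomer subunits. Of 5 signal peptidase genes, 2 were called low, while SPCS1 (−0.23 ± 0.30) and SEC11C (−0.17 ± 0.18) were not called. SPCS3 had a mean of −1.68 ± 0.36 at its first promoter and SEC11A −1.53 ± 0.67, both with a permutation p of 2e-05 (adjusted p = 0.0147). The second promoter of SPCS3 had a mean of −0.25 ± 0.30 and was not called, and both promoters pooled gave −0.97. SPCS2, at −1.03 ± 0.34, was called only adjusted over the list alone (adjusted permutation p = 0.00393). The whole list of 31 genes of the Sec61 channel, the signal recognition particle and membrane insertion had a median of 0.02, at the 51st percentile. The channel subunit SEC61A1, at 0.72 ± 0.17, was called high adjusted over that list alone (permutation test, adjusted p = 0.0408). SPPL3, an intramembrane protease that cleaves glycosyltransferases, had a mean of −1.37 ± 0.28 (permutation p = 6e-05, adjusted p = 0.0293). It was the called member among 12 genes of glycosphingolipid synthesis, whose median was −0.04, at the 19th percentile.

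The MHC-I high direction was led by genes of diverse function. CASP8AP2, which acts in histone gene expression, had a mean of 2.46 ± 0.68, a 5.51-fold excess in MHC-I high, at a mean count of 483 reads per guide. JUNB had a mean of 2.31 ± 0.49 and B3GNT2, which extends poly-N-acetyllactosamine chains, 2.21 ± 0.25. FAM3A had a mean of 1.85 ± 0.23, CAD, the enzyme that starts pyrimidine synthesis, 1.76 ± 0.30, and SCFD1, a regulator of ER to Golgi fusion, 1.58 ± 0.19. For each of these 6 genes 5 of 5 guides lay above 0 and the permutation p was 2e-05 (adjusted p = 0.0147). RRM1, the large subunit of ribonucleotide reductase, had a mean of 1.57 ± 0.53 with 4 of 5 guides above 0 at a mean count of only 147 reads, too few for the 500-read filter. PNISR (1.35 ± 0.38 at its first promoter) and the elongation factor SUPT5H (1.29 ± 0.18) were called with the same permutation p of 2e-05. PNISR moved to 0.72 and lost its call with both promoters pooled. The ribosome recycling factor ABCE1 (1.25 ± 0.44) and FXYD5 (1.23 ± 0.83) had a permutation p of 4e-05 (adjusted p = 0.0216). ABCE1 moved to 0.67 with the median of its guides and was not called, and its guides overlap in position with those of ANAPC10, which had a mean of 0.27 ± 0.18. The FXYD5 value rested on 1 guide with 0 reads in MHC-I low and 188 in MHC-I high, and without the farthest guide it was 0.44 and not called.

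**Figure D2:**
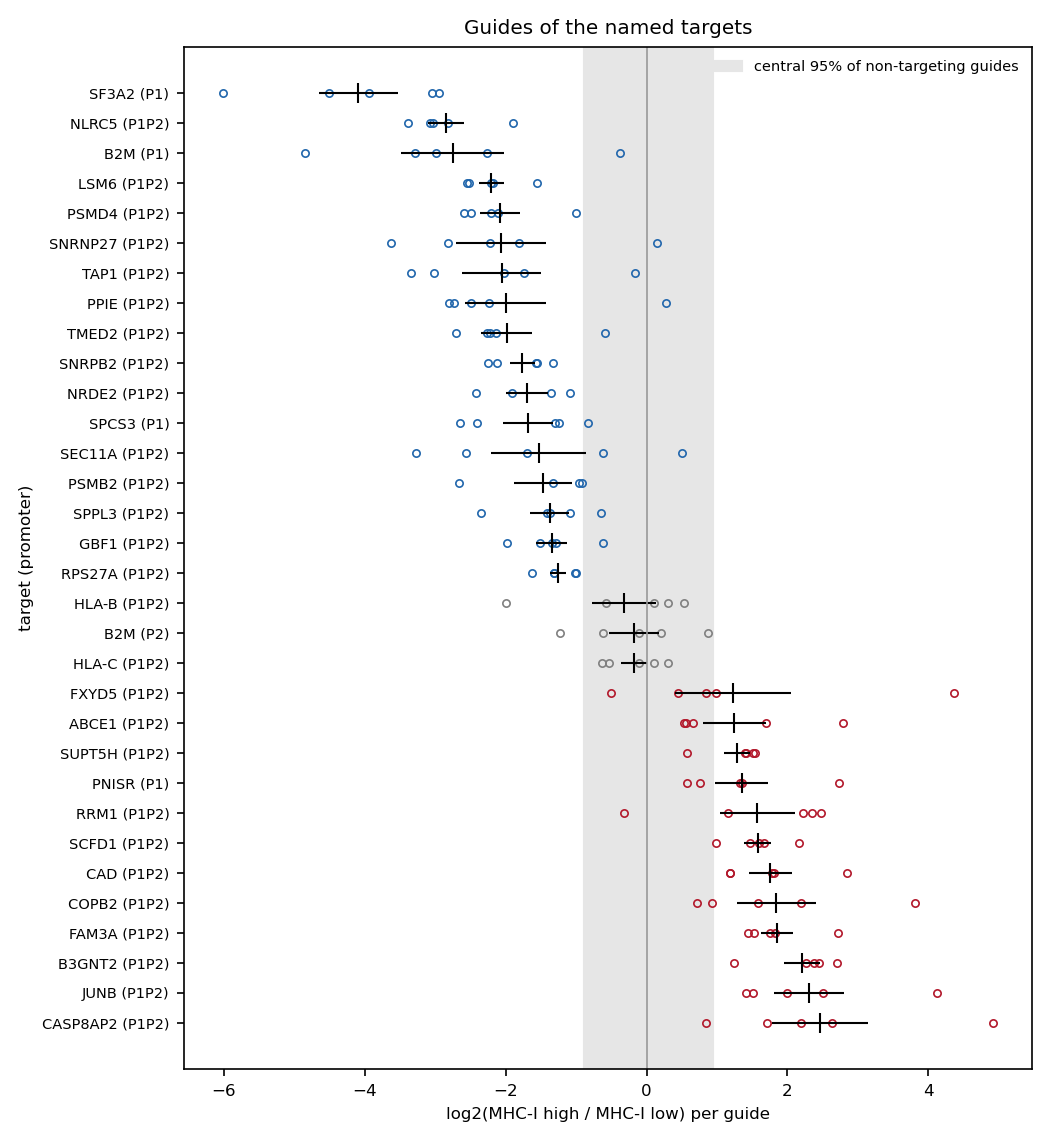
Log2(MHC-I high / MHC-I low) of single guides (horizontal axis) for the targets named in the text (vertical axis), with open circles for guides and black bars for the mean ± SE. Blue and red mark targets called low and high, grey marks targets not called, and the grey band holds the central 95% of non-targeting guides, −0.89 to 0.95. All 5 NLRC5 guides lie below the band, while for SNRNP27, PPIE and SEC11A 1 guide of 5 lies above 0.

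Signalling lists with no called member over all targets differed in their medians. The 25 genes of mTORC1 and nutrient signalling had a median of 0.23, at the 99.99th percentile, with 21 above 0. Without the farthest guide of each target that median was 0.09, at the 98.3rd percentile. Adjusted over the list alone, 4 of them were called high: LAMTOR3 (1.09 ± 0.65), LAMTOR2 (0.95 ± 0.32) and LAMTOR1 (0.73 ± 0.20), subunits of the Ragulator complex, and the kinase MTOR (0.86 ± 0.40). The 23 genes of EGFR, RAS and MAPK signalling had a median of 0.13, at the 98.6th percentile, with 17 above 0. The kinase BRAF, at 0.98 ± 0.29, was called high adjusted over the list alone (permutation test, adjusted p = 0.0106). That median was 0.08 with the median of the guides and 0.07 without the farthest guide, both inside the range of random lists. Interferon and JAK-STAT genes had a median of −0.01, at the 30.3rd percentile, and their most extreme member was SOCS3 at 0.63 ± 0.51. With 8 members below 0 and 7 above, that median does not tell whether members with opposed roles lay on opposed sides. The median of NF-kB genes was 0.02, at the 49.1st percentile, with NFKB2 as the most extreme at 0.71 ± 0.20. With 10 members below 0 and 11 above, that median likewise does not tell whether members with opposed roles lay on opposed sides. The kinase MAP3K14 lay lowest, at −0.56 ± 0.12. Members were not tested apart by role, and none was called adjusted over the list alone. Chromatin repressors, among them the PRC2 complex, had a median of −0.04, at the 11.3rd percentile, with PCGF1 at −0.45 ± 0.20.

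Lists of protein quality control and turnover held no member called over all targets. Core autophagy genes had a median of −0.11, at the 0.07th percentile, with 23 of 37 below 0, and the lipid kinase PIK3C3 was the most extreme at −0.54 ± 0.41. That median was −0.05, inside the range of random lists, without the farthest guide. The 19 autophagy and ER-phagy receptors had a median of −0.03, at the 17.8th percentile. Their most extreme member was TAX1BP1 at −0.45 ± 0.21, and IRGQ was at −0.03 ± 0.20 over 4 guides, a gene chosen after its value was seen. ER-associated degradation genes had a median of 0.04, at the 64.3rd percentile, with SEL1L at −0.42 ± 0.20. The 36 genes of N-glycan assembly had a median of 0.11, at the 98.7th percentile, which became 0.03 without the farthest guide. Among them DAD1, a subunit of the oligosaccharyltransferase, had a mean of 0.92 ± 0.21 and was called adjusted over the list alone. Surface MHC-I turnover genes had a median of 0.07, at the 84.1st percentile, and the retromer subunit VPS29 (0.95 ± 0.12) was called adjusted over the list alone. In this list WWP2 (0.58 ± 0.26), SUSD6 (0.52 ± 0.11) and TMEM127 (0.50 ± 0.41) followed and were not called, genes chosen after their values were seen. The medians of lysosome acidification, UFMylation and the unfolded protein response were 0.02, −0.03 and 0.03, at percentiles of 47.7, 25.5 and 56.6. Their most extreme members were VPS16 (0.44 ± 0.17), UFSP1 (−0.33 ± 0.14) and HSP90B1 (0.50 ± 0.16). The unfolded protein response median moved to 0.14 with the median of the guides, at the 97th percentile. Without the farthest guide it was 0.16, at the 100th percentile and outside the range of random lists.

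The 82 cytosolic ribosomal proteins, a list of genes needed for growth, had a median of 0.01, at the 37.4th percentile, with 41 members on each side of 0. RPS27A, a fusion of ubiquitin with a small subunit protein, was the called member, with a mean of −1.25 ± 0.12 and 5 of 5 guides below 0 (permutation p = 0.00012, adjusted p = 0.0483). It lost this call without the count filter at an unchanged mean of −1.25. RPS19 (−0.89 ± 0.31) was also called low adjusted over the list alone, and RPL34 (0.88 ± 0.29) was called high in that way. The 365 olfactory receptors had a median of 0.02, at the 48.8th percentile, and none was called, with OR2C3 as the most extreme at −0.82 ± 0.46.

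**Figure D3:**
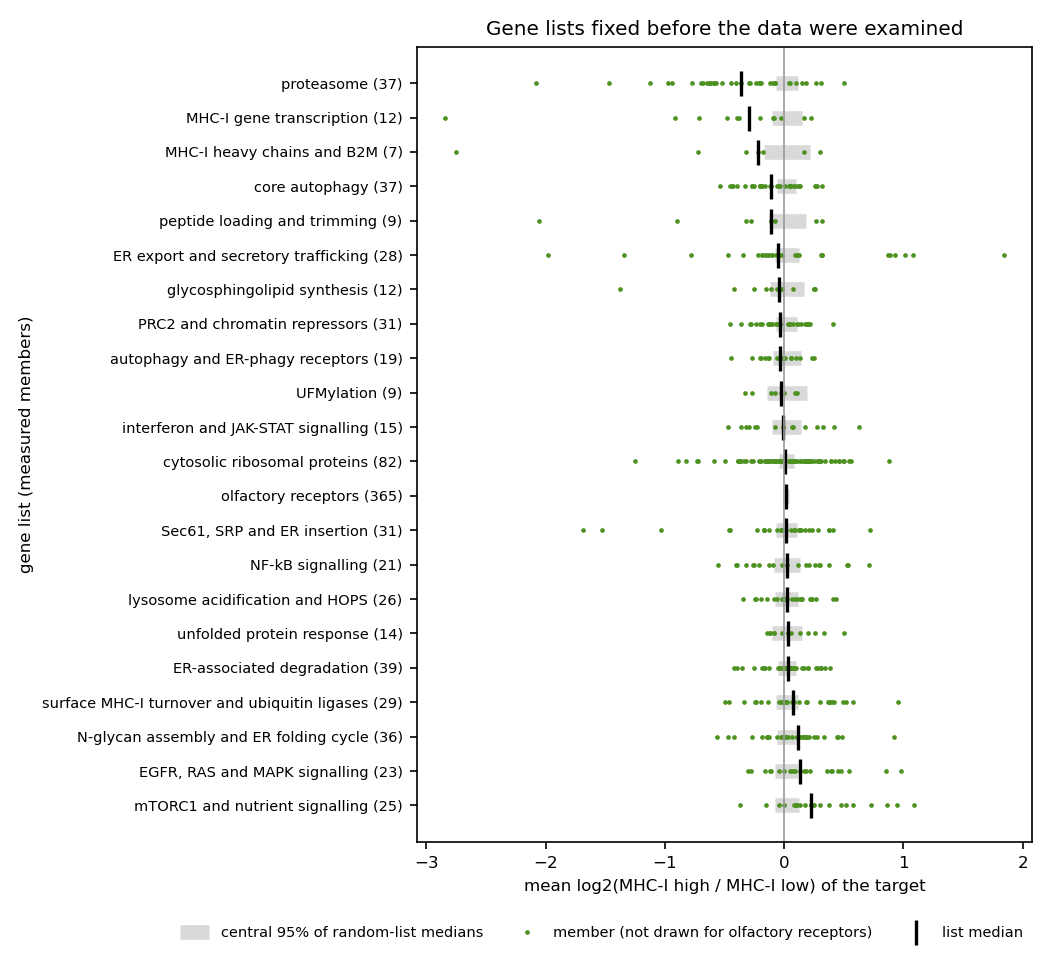
Mean log2(MHC-I high / MHC-I low) per target (horizontal axis) for the 22 gene lists fixed in advance (vertical axis, measured members in brackets). Green points are members, black bars list medians and grey bands the central 95% of 10000 random lists matched on read count. The proteasome median of −0.37 lies below its band and the mTORC1 median of 0.23 above its band.

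With a pseudocount of 1 in place of 10, 18 of the 29 called targets named by the fixed rule lost their call with no change of direction. The p-values compare these 2 libraries, and no value here has a check against a repeated sort.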

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

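The alternatives with 2000000 draws, with scaled guide values and with null guides matched on read count were chosen after the results had been seen, and all others before the data were examined. No paired analysis was possible because each sort has 1 library, and for the same reason no replicate could be left out. The counts of 34 targets called low and 17 called high became 52 and 82 under the 500-read filter, 3 and 11 with a pseudocount of 1, and 74 and 55 with a pseudocount of 50. They became 57 and 30 with the median of the guides and 52 and 34 without the guide farthest from 0. The 3 guides farthest from 0 gave 15 called low, and all guides as the null gave 10 called high. Division by the SD of the non-targeting guides in the same 1 of 5 bins of read count gave 95 and 49, of which 32 and 13 were among the main calls. That SD is 1 value for the whole lowest bin and so too small for the guides with the fewest reads. A null of the 30 non-targeting guides nearest in read count gave 165 and 136, of which 32 and 15 were among the main calls, and in the simulation it made 132 false calls among 280. An adjusted p of 0.01 left 0 and 0 in the main permutation test. There the smallest p that 100000 draws can give came to an adjusted p of 0.0147. With 2000000 draws the threshold of 0.01 left 17 and 8. The Mann-Whitney test called 0 and 0, with 696 and 662 targets at an unadjusted p of 0.05, and it recovered 0% of the changed targets in the simulation. The cause of the other changes was not tested. The counts kept within 1.5 times of the main ones in the remaining settings. Across 13 settings, leaving aside pooling, the threshold and the Mann-Whitney test, 9 targets were called in each: B2M, NLRC5, SF3A2, B3GNT2, CAD, CASP8AP2, COPB2, FAM3A and JUNB. Over 261 comparisons of named targets with their main value, 230 kept direction and side of the threshold, 27 lost the call (18 of them with a pseudocount of 1), 1 gained it by pooling of the 2 B2M promoters and 3 changed sign. HLA-B changed sign to 0.111 with the median of the guides and to 0.0927 without the farthest guide, and the second B2M promoter to 0.0875 without it. Of 176 list medians, 169 kept their side of the random range. With the median of the guides, the medians of the heavy chains and B2M (−0.101) and of EGFR, RAS and MAPK signalling (0.0771) came inside it. Without the farthest guide, those 2 (−0.0586 and 0.0697), N-glycan assembly (0.0252) and core autophagy (−0.0478) came inside it, and the unfolded protein response left it (0.16). The SD of the non-targeting guides was 0.42 under the 500-read filter, 0.55 with a pseudocount of 1 and 0.43 with a pseudocount of 50. Depth limited the guides with few reads: 3 named targets, LSM6, NRDE2 and RRM1, could not be tested under the 500-read filter.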

Other observations

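The gene lists in this part other than ER export and ribosomal proteins were assembled after the called targets had been seen, and the test of coatomer guides with many reads, the test against non-targeting guides of like read count and the medians of the replication, Integrator and SNARE lists without called members were chosen after the results they bear on.

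Genes of DNA replication and nucleotide supply lay towards MHC-I high. Of 30 such genes 28 were above 0, and the median of 0.23 was higher than in any of 10000 random lists matched on read count. Without CAD and RRM1, the members called over all targets, 26 of 28 were above 0 and the median was 0.19, at the 99.99th percentile. Of the other members, GINS1 (0.78 ± 0.21), UMPS (0.74 ± 0.42) and POLE (0.68 ± 0.23) were called adjusted over the list alone. The 12 Integrator subunits, which process small nuclear RNAs and end transcription early, had a median of −0.57 with 11 below 0, and INTS2 was called low at −1.25 ± 0.40 (permutation p = 0.00012, adjusted p = 0.0483). In the same list of 21 genes the elongation factors SUPT5H, SUPT6H (0.91 ± 0.31) and SUPT4H1 (0.27 ± 0.26) lay above 0. The whole list had a median of −0.14, at the 0.28th percentile, and without its 2 called members −0.14, at the 0.41st percentile. The 24 SNAREs and tethers between the ER and the Golgi had a median of 0.11, at the 96.8th percentile, and without the called member SCFD1 a median of 0.09, at the 92.4th percentile.

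In the LSm2-8 ring that binds U6 RNA, 6 of 7 subunits were below 0 and 5 were called low, while LSM3 was at 0.01 ± 0.62. The called ones were LSM2 (−1.40 ± 0.49), LSM5 (−1.66 ± 0.48 at its first promoter, −0.61 ± 0.17 and not called at its second), LSM6, LSM7 (−1.45 ± 0.19) and LSM8 (−1.51 ± 0.40). LSM1, which takes the place of LSM8 in the cytoplasmic ring for mRNA decay, was at 0.22 ± 0.10. All 5 signal peptidase subunits were below 0, with a median of −1.03, but SPCS1 and SEC11C lay near 0 with 3 of 5 guides below it. The ribosomal list was split by subunit after a difference had been noticed in the data, so the percentiles of its parts are descriptive only. Small ribosomal subunit proteins had a median of −0.15, at the 0.03rd percentile, with 23 of 33 below 0. Large subunit proteins had a median of 0.12, at the 99th percentile, with 31 of 49 above 0. The 4 members of the chromosomal passenger complex, CDCA8, BIRC5, AURKB and INCENP, were all above 0, with a median of 0.83. This complex was also singled out after its values had been noticed. Its called member CDCA8 (1.17 ± 0.84) had 3 of 5 guides above 0 and was called in 6 of 13 settings.

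Spliceosome genes lay towards MHC-I low, with 60 of 70 below 0, a median of −0.48 and 15 called. Few reads per guide are argued against as the cause: the 55 members that were not called still had a median of −0.287, lower than in any read-matched random list (central 95% from −0.05 to 0.09). A general loss of fitness was not excluded. The cytosolic ribosomal proteins had a median of 0.011 (bootstrap 95% from −0.07 to 0.09), above the −0.24 that marks the midpoint between 0 and the spliceosome median. By the bound set beforehand, which used that bootstrap, the ribosomal median went against this explanation. Single members lay on both sides of 0, with an SD of 0.35, which is their spread and not the error of the median. The small subunit proteins, a part noticed in the data, lay on the spliceosome side at −0.15. A fitness effect unlike that of the whole ribosomal list is therefore not excluded. In the sorted libraries, guides against ribosomal proteins had a median count of 82.8% of that of non-targeting guides, and spliceosome guides 88.9%, with their starting abundance not analysed here. No biological explanation was tested, since the design holds no measure of splicing, and a repeated sort would be needed to tell whether the pattern recurs.

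Coatomer subunits lay towards MHC-I high, with 6 of 7 above 0 and COPE at −0.35 ± 0.30, while TMED2 and GBF1 of the same list were called low. The coatomer median was 0.93, over subunits singled out because they lay high. Among random lists matched on read count it lay at the 100th percentile (central 95% from −0.23 to 0.26). That place goes against few reads alone, though the choice of high subunits favours it. Few reads per guide stay open as the cause: of 35 coatomer guides only 6 had at least the median count of non-targeting guides (a mean of 1284 reads over the libraries), and their median was 0.09, with 3 above 0 and a bootstrap 95% over subunits from −0.15 to 1.57. Guides that act on a gene needed for growth would also lose reads, and so few guides cannot separate these explanations. The ribosomal median of 0.011 (bootstrap 95% from −0.07 to 0.09) lay below the 0.46 that a comparable shift would need. By the bound set beforehand, which used that bootstrap, this argues against a general loss of fitness of the size seen for ribosomal proteins. Single ribosomal members spread with an SD of 0.35, and the large subunit had a median of 0.12. However, coatomer guides had fewer reads in the sorted libraries than ribosomal ones, at 67.7% of the non-targeting median count. Whether this reflects loss of cells or a lower starting abundance was not tested, so a fitness effect stronger than that of ribosomal proteins stays open, and no biological explanation was tested.

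Some called targets rested on guides with few reads: 8 of the 51 had a mean count under 500 per guide. The SD of non-targeting guides was 2.76 times as large in the fifth with the fewest reads as in the fifth with the most, so a wider spread may account for part of these calls. Under the 500-read filter 5 of the 8 were lost, 3 of them because too few guides were left to test, against 6 of the other 43. When each guide was set against the 30 non-targeting guides nearest to it in read count, 6 of the 8 stayed called. That test was loose: in the simulation it called 132 of 20325 unchanged targets, 1 of them among the 118 under 500 reads, and the simulated noise of guides with few reads was drawn from all non-targeting guides in the fifth with the fewest reads, so it may be narrower than theirs. SF3A2, LSM6, NSRP1 and CASP8AP2 had the lowest adjusted permutation p that it gave, 0.00309, which argues against the wider spread as the only cause for these 4. It stays open for NRDE2 and RRM1, which were lost, and for SLC34A3 and SLC7A6, which passed at an adjusted permutation p of 0.0451 and 0.0281.

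A first hypothesis was that knockdowns that stop division may leave larger cells with more surface MHC-I. A list of 24 cell division genes had a median of 0.04, at the 62.5th percentile, and without the called member CDCA8 the median was 0.004, at the 38.1st percentile. The hypothesis was not borne out for the list. By the bound set beforehand the prediction failed for its median. Adjusted over the list alone, 2 members were called low and 6 were called high. The list of DNA replication and nucleotide supply, with 28 of 30 genes above 0, was not part of this prediction. The hypothesis is not excluded for single genes, because members lay on both sides of 0 (SPC25 at −0.70 ± 0.23, BIRC5 at 0.93 ± 0.38) and cell size was not measured.

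A second hypothesis started from B3GNT2 and GCNT2 (1.16 ± 0.30 at its first promoter, permutation p = 0.0001, adjusted p = 0.0456, and 0.08 ± 0.26 at its second), which build and branch lactosamine chains, and from SPPL3, which lay on the opposite side. It held that loss of N-glycan elongation may raise MHC-I staining. The 19 genes of N-glycan branching, elongation and sialylation had a median of 0.08, at the 86.2nd percentile, and without the 2 called members the median was −0.04, at the 14.7th percentile. The list as a whole did not bear the hypothesis out. MGAT5 (0.76 ± 0.40) and SLC35A3 (0.68 ± 0.21) passed adjusted over the list alone while the sialylation gene ST6GAL1 was at −0.38 ± 0.15. By the bound set beforehand the prediction failed for the list. The median averaged members of different steps, so the hypothesis is not excluded for single steps, which were not tested apart.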
